A study of Rattus norvegicus with 2 samples.

How the data were processed

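The series holds 2 RNA-seq libraries of primary adult rat OPCs, 1 with Aβ and 1 with DMSO. Per the labels' protocols, 1 µg of total RNA went into each mRNA library. The treatment text of both samples names Aβ exposure, so the control group was taken from the treatment label, which gives DMSO. Reads were aligned with Bowtie2 to Rnor_6.0, per the submitters' processing notes; the version, the counting tool and the gene annotation are not given in the sources used here.

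The authors' deposited expression table gives an estimated count of reads for each of 17049 genes, named by symbol and gene number. The deposited estimated counts are not whole for 1979 genes (11.6%) in the Aβ library and 2074 (12.2%) in the control library, which hold 13.1% and 12.3% of the reads. These are called divided reads here, since estimated counts of this kind can share reads among gene models with common sequence, and a gene is counted so if either library's value is not whole. The authors also give TPM, which sums to the same total in each library up to rounding, and FPKM, which is proportional to TPM within a library. A further pair of deposited columns is named normalized read count, but each value is the read count rounded up in all 17049 rows, so it was treated as a score and not used. A deposited enrichment table gives, per the file headers, gene ontology terms with numbers of genes, fold enrichment ratio, p-value, adjusted p-value, q-value and z score. It is labelled as covering genes higher with Aβ, and the further rule that picked its 391 genes is not given in the sources used here.

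The totals were 15704932 estimated reads (Aβ) and 15663751 (control). The 10 most abundant genes held 4.39% and 4.49% of them, and ribosomal protein genes 3.69% and 3.60%. A count of 0 allows up to 3 reads, or 0.191 CPM (reads scaled to the library total) with Aβ and 0.192 CPM in the control.

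The ratio of a gene was log2((Aβ TPM + 1)/(control TPM + 1)), computed for 12980 genes at 1 TPM or more in either library, and the rule of size was 2-fold. A pseudocount of 1, also used with CPM, understates the ratio of low genes. The plan allowed FPKM, TPM or CPM without choosing among them, and TPM was taken when the table was found to hold more than 1 of these. Read ratios are Aβ over control in reads per total reads, with exact Clopper-Pearson 95% intervals of the conditional binomial, from reads rounded to whole numbers. A gene is called higher or lower by reads where that interval excludes 1. Reads without molecular identifiers are not independent molecules, so the intervals cover counting error only. These intervals compare 2 libraries, not the conditions.

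Before the data were examined, 37 gene lists were fixed: OPC markers, committed and newly formed oligodendrocytes, myelin, cholesterol biosynthesis, inflammatory genes, interferon response, antigen processing, complement, pattern recognition, actomyosin, SRF and YAP targets, Arp2/3 and actin turnover, integrins, matrix, inhibitors of differentiation, cell cycle, p53, unfolded protein response, heat shock, oxidative stress, immediate early genes, glycolysis, oxidative phosphorylation, lysosome and lipid handling, amyloid genes, disease-associated oligodendrocytes, microglia, astrocytes, neurons, endothelium, pericytes, fibroblasts, Schwann cells, ependyma, blood and T cells, sex-linked transcripts and housekeeping genes. For each, the median log2 ratio of measured members (1 TPM or more in either library) is given with a binomial order-statistic 95% interval, which for lists under 6 members is their range. Its percentile among 10000 random lists, matched in 20 bins of mean expression, describes these 2 libraries and is not a test. Some lists share members, such as the 4 genes common to the contractile and pericyte lists.

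Named genes followed a rule fixed at the same time: among genes with a symbol that is not a predicted locus, at 5 TPM or more, the 15 highest and 15 lowest; in each list the 4 with the largest absolute log2 ratio; and 21 genes always named, 177 genes in all, of which some are not reported here. Il11, Nrn1, Bhlhe40 and the further list members named (Il1a, Cxcl2, Ccl3, Nos2, Lcn2, Cxcl11, Csf1, Il33 and Srebf2) were chosen after their values were seen, as was the summing of Myh9 and Myh9l1. A RefSeq gene table of another build (GRCr8) was used for names only and no coordinates are printed; 15987 gene numbers were found in it, 14393 with the same symbol, and 1062 were not found. That table gives Myh9l1 as an older name of Myh9.

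The steps were tested on counts simulated from these 2 libraries, over 17049 genes with 200 of them altered. The 2-fold rule recovered 43 of 50 genes raised 2.5-fold (86%), 50 of 50 raised 4-fold, 47 of 50 lowered to 0.25-fold (94%) and 0 of 50 raised 1.5-fold. It called 27 of 12694 unaltered genes (0.213%) and 0 of 10420 with 200 or more reads, and the intervals held the true ratio for 95.3% of the latter. Of 200 random lists with no effect, 15 (7.5%) lay outside the central 95% of their random lists. Of lists drawn from well-expressed genes and raised 1.3-fold by adding to their log2 ratios, 50 of 50 lay above the 97.5th percentile. Raised lists of low genes were not simulated. The simulated counts held counting error only, without divided reads or culture differences, so these rates do not carry over to genes with either.

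Alternatives were other pseudocounts, filters, folds and scalings, CPM from the read counts for the 2-fold counts, and means in place of medians. No mitochondrially encoded gene was found by symbol, so the setting without abundant genes left out 113 ribosomal protein and highly expressed genes. Added after seeing the data were CPM for gene lists and named genes, FPKM, whole reads only, and 50 or more whole reads with 2-fold by TPM and CPM. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.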

Results

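RNA was sequenced from primary oligodendrocyte precursor cells (OPCs) of adult wild-type rat brain. OPCs are the dividing glial cells that give rise to myelinating oligodendrocytes. The cells were kept in OGM medium at 37 °C and 5% CO2, and 1 culture was exposed to 1 µM amyloid-β (Aβ), the peptide of Alzheimer's plaques, for 2 days. The control culture received DMSO, a solvent. Each group had 1 library, with 15704932 estimated reads for Aβ and 15663751 for the control, over 17049 genes. A level of 1 or more TPM, a unit corrected for gene length and library total, was reached by 12734 genes in the Aβ library and 12776 in the control library. The comparison addresses how OPCs respond to Aβ, with inflammation, contraction of the cytoskeleton and differentiation named in the study's title. With 1 library per group no difference had a replicate check, so no p-value or standard error is given, and each 95% interval of a read ratio covers counting error only.

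Among genes with whole read numbers and 50 or more reads over both libraries, 7 were at least 2-fold higher in the Aβ library by TPM and by reads scaled to the library total (CPM), and 1 was lower. Both ratios carried a pseudocount of 1, so low genes 2-fold apart by reads could miss this rule, and the split of 7 and 1 depends on it. Such genes included Slc24a2 (read ratio 0.427), Col1a1 (0.425) and Stab1 (0.497) below 1, and Arc (2.01) and Chac1 (2.66) above. Nr4a1, an orphan nuclear receptor of the immediate early class, was at 31.3 TPM with Aβ and 11.1 TPM in the control, a read ratio of 2.81 (95% interval 2.43 to 3.26). Ptgs2 (cyclooxygenase-2) and Ptges (prostaglandin E synthase), consecutive enzymes of prostaglandin E2 synthesis, had read ratios of 2.40 (1.83 to 3.18) and 2.56 (1.73 to 3.85). The cytokines Il6 and Il11 had ratios of 2.19 (1.71 to 2.81) and 2.17 (1.85 to 2.56). Nrn1 (neuritin) was at 2.26 (1.84 to 2.79) and the transcriptional repressor Bhlhe40 at 2.04 (1.83 to 2.28). Cxcl13, a chemokine for B cells, was lower with Aβ, at 1.89 TPM against 7.75 TPM and a read ratio of 0.246 (0.133 to 0.429). The gene numbers are 79240 for Nr4a1, 29527 for Ptgs2, 59103 for Ptges, 24498 for Il6, 171040 for Il11, 83834 for Nrn1, 79431 for Bhlhe40 and 498335 for Cxcl13.

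Across the transcriptome most genes lay close to equal. Of 12980 genes at 1 TPM or more in either library, 65 were at least 2-fold higher and 64 at least 2-fold lower with Aβ, and 99.0% lay within 2-fold. The median log2 ratio was 0.01, and the central 95% of genes ran from 0.734-fold to 1.39-fold. The levels correlated across genes with Pearson's r = 0.991 and Spearman's rho = 0.993, over genes that are not independent replicates. The read requirement that left the 8 genes above was added after the data were seen. Of the 129 genes 2-fold apart by TPM, 79 (61.2%) had divided reads, that is, counts that were not whole, against 13.5% of all genes kept, and 51 had 0 reads in 1 library. Sequence shared between gene models was not checked. Among 9307 genes with whole reads and at least 200 reads in both libraries together, the counting interval excluded equality for 2415 (25.9%), where counting error alone gives 5%. Of these, 1167 were higher and 1248 lower with Aβ.

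**Figure D1:**
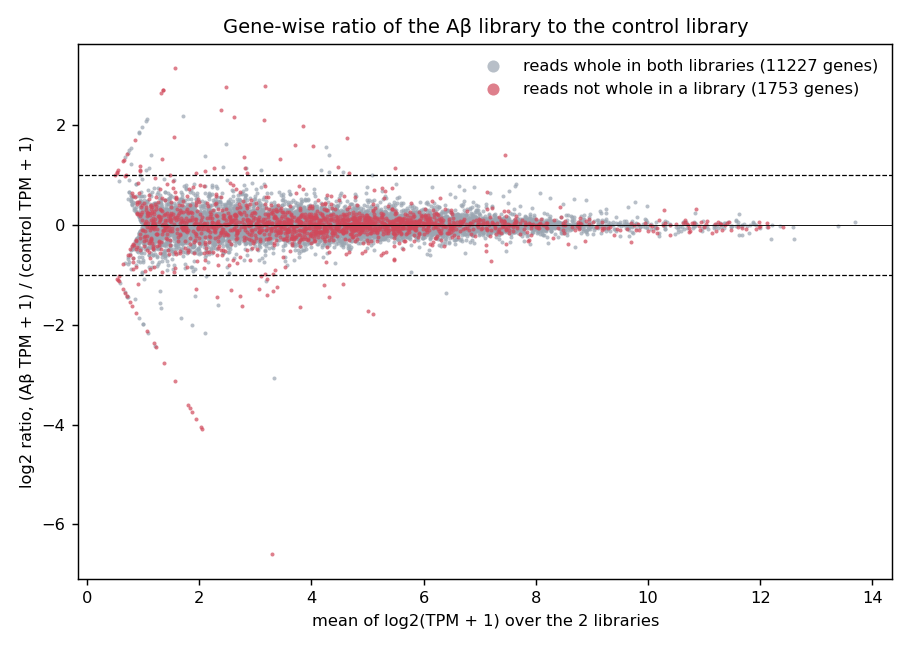
Each point is 1 of the 12980 genes at 1 TPM or more in either library; the x axis is the mean of log2(TPM + 1) over the 2 libraries and the y axis the log2 ratio of Aβ to control, with dashed lines at 2-fold. Genes with divided reads (red, 1753 genes) make up 79 of the 129 points beyond the dashed lines.

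The ends of the ranking by TPM were held mostly by genes with divided reads. Of the 15 named genes with the highest ratio, 11 had such reads, among them Vwa5a, Gstm5, Cbr1, Tnf, Moap1, Alkbh6, Myh9l1, Mt1m, Polr2i and Echs1. Vwa5a was estimated at 898.75 reads with Aβ and 99.36 in the control. The other members of this end were Nr4a1, Ptges, Csf2 with 13 and 3 reads, and Ccl6 with 4 and 1. Among the 15 lowest, 8 had divided reads. Gcs1, Hist2h2aa3, Ppp1r35 and gene-Mrgbp, 4 of these, were listed at 0 reads with Aβ, and Clip3, Mrpl1 and Nol8 were also among them. Vamp5 (1 read with Aβ against 10 in the control), Riiad1 (6 against 17), Hist1h2ail1 and Npff (1 against 7 each) and Hes5 (4 against 15) rested on few reads. Fxyd2 was at 52.0 TPM with Aβ and 134.6 TPM in the control, yet had 194 and 184 reads, a read ratio of 1.05 (0.855 to 1.29).

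Inflammatory genes were higher in the Aβ library as a group. Of 40 measured cytokines, chemokines and NF-κB targets, 35 were higher and 5 lower, with a median log2 ratio of 0.33 (95% order-statistic interval over genes 0.20 to 0.49), or 1.25-fold. That median stood at percentile 100 of 10000 random lists matched on expression. The read interval lay above 1 for 26 members and below 1 for 2, and 4 members were 2-fold higher (Tnf, Csf2, Ptgs2 and Il6). The pyrogenic cytokine Il1b was at 260 TPM with Aβ and 149 TPM in the control (read ratio 1.74, 1.64 to 1.85), and the monocyte chemokine Ccl2 at 415 and 310 TPM (1.36, 1.27 to 1.46). Among members picked after their values were seen, Il1a had a read ratio of 1.78 (1.61 to 1.97) and the neutrophil chemokine Cxcl2 of 1.75 (1.59 to 1.94). Ccl3, also picked so, was at 1.60 (1.47 to 1.73). Inducible nitric oxide synthase Nos2, picked likewise and with divided reads, was at 1.51 (1.36 to 1.69). Nfkbia, the NF-κB inhibitor, was at 1.07 (0.994 to 1.14). The members lower with Aβ were Cxcl11, Lcn2, Cxcl10, Csf1 and Il33, and Cxcl10 had 74 and 88 reads (0.839, 0.607 to 1.16). Tnf was listed at 76.02 reads with Aβ and 0 in the control, while LOC103694380 had 150.98 and 187.00, and the sums of 227 and 187 gave a ratio of 1.21 (0.993 to 1.48). The microglia marker list, measured in the same libraries, had a median log2 ratio of 0.02 (−0.31 to 0.08).

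Pattern recognition receptors and inflammasome genes went both ways, with 14 of 27 higher and a median log2 ratio of 0.02 (−0.06 to 0.18, percentile 65.3) and a read interval above 1 for 5 and below 1 for 2. The inflammasome sensor Nlrp3 was higher with Aβ (read ratio 1.95, 1.54 to 2.48), as was the lipopolysaccharide co-receptor Cd14 (1.39, 1.26 to 1.53). Tlr4 was lower on 30 and 50 reads (0.598, 0.367 to 0.960), and Pycard had only 5 and 1 reads.

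Immediate early genes were higher with Aβ. Of 22 measured, 19 were higher and 3 lower, the median log2 ratio was 0.27 (0.12 to 0.50) at percentile 100, and the read interval lay above 1 for 14 and below 1 for 0. After Nr4a1 the largest ratios were those of Arc at 2.01 (1.52 to 2.68), Nr4a2 at 1.93 (1.56 to 2.39) and the phosphatase gene Dusp5 at 1.61 (1.33 to 1.95). Egr1 was at 77.1 and 55.6 TPM (1.38, 1.26 to 1.53). Genes of the unfolded protein and integrated stress response were slightly higher, with 18 of 24 higher, a median log2 ratio of 0.07 (0.02 to 0.22) and percentile 99.6, and a read interval above 1 for 10 and below 1 for 3. In that list Chac1, on 40 and 15 reads, had a ratio of 2.66 (1.44 to 5.18), asparagine synthetase Asns 1.34 (1.21 to 1.49) and Ero1b 1.27 (1.07 to 1.5), while Atf3, with divided reads, had 1.32 (0.930 to 1.90). Neuron markers had a median log2 ratio of 0.10 (−0.03 to 0.50, percentile 94.6, 14 measured). Snap25 (1.5, 1.16 to 1.96), Celf4 (1.72, 1.16 to 2.56) and Rbfox3 (1.85, 1.06 to 3.31) were higher with Aβ, and Syt1 was lower (0.490, 0.297 to 0.790), at 8.47 TPM or less in either library.

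Cholesterol biosynthesis genes were all higher in the Aβ library. The 24 measured members had a median log2 ratio of 0.36 (0.31 to 0.40), or 1.29-fold, at percentile 100, and the read interval lay above 1 for 23 of them. Idi1, the isopentenyl diphosphate isomerase, was at 209 and 140 TPM (read ratio 1.49, 1.43 to 1.55). Msmo1, a sterol oxidase, was at 1.37 (1.34 to 1.41) and lanosterol synthase Lss at 1.37 (1.31 to 1.44). Srebf2, the transcription factor of the pathway, picked after its values were seen, was at 1.04 (1.00 to 1.08). No member reached 2-fold. Lysosome and lipid handling genes had a median log2 ratio of 0.06 (0.00 to 0.16, percentile 98.1), with 19 of 24 higher and a read interval above 1 for 9 and below 1 for 4. The fatty acid genes Scd (1.24, 1.19 to 1.28) and Fasn (1.18, 1.15 to 1.21) and the protease gene Ctsz (1.20, 1.11 to 1.29) were higher, and Srebf1, a regulator of fatty acid synthesis, was lower (0.766, 0.718 to 0.818). Scd and Srebf1 had divided reads.

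Interferon response genes were lower with Aβ. Of 31 measured, 27 were lower and 3 higher, with a median log2 ratio of −0.19 (−0.30 to −0.11) at percentile 0. The read interval lay below 1 for 6 members and above 1 for 2. Mx2, an antiviral GTPase, was at 9.15 and 15.4 TPM (read ratio 0.579, 0.489 to 0.684) and Ifi27 at 147 and 212 TPM (0.705, 0.641 to 0.774). Oas1a had 21 and 34 reads (0.616, 0.340 to 1.09). Ifit3 went the other way on 33 and 14 reads (2.35, 1.22 to 4.75). Antigen processing genes had a median of −0.04 (−0.18 to 0.07, percentile 13.6), with 11 of 20 lower. Among them Tap2 was at 0.818 (0.684 to 0.978), RT1-S3 at 0.711 (0.518 to 0.972) and RT1-DMa at 0.772 (0.593 to 1.00), while Cd86 had 8 and 12 reads. Divided reads were held by 8 of the 20, Tap2 and RT1-DMa among them. Complement genes had a median of −0.05 (−0.42 to 0.20, percentile 19.7, 10 measured). Serping1, the C1 inhibitor, was lower at 0.725 (0.588 to 0.893), as was C4a, on divided reads, at 0.545 (0.351 to 0.836). C1s (1.18, 0.918 to 1.51) and Cd59 (1.18, 0.838 to 1.68) were within counting error of equal.

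**Figure D2:**
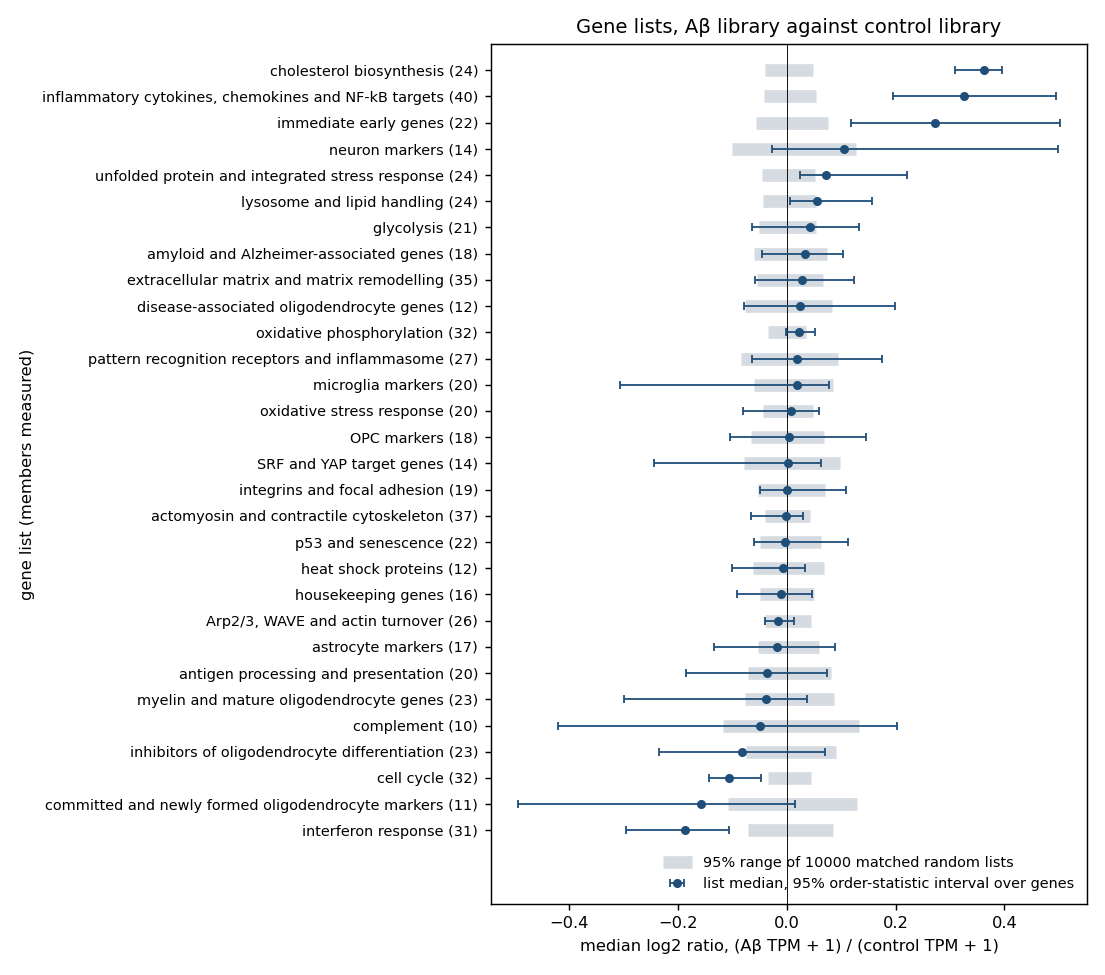
Points are the median log2 ratio of Aβ to control over the measured members of each gene list with at least 10 such members (number in parentheses), bars the 95% order-statistic interval over genes, and grey bands the 95% range of 10000 random lists matched on expression. The cholesterol (0.36), inflammatory (0.33) and immediate early (0.27) lists lie to the right of their bands, as do, by less, the unfolded protein (0.07) and lysosome (0.06) lists, and the interferon (−0.19), committed oligodendrocyte (−0.16), cell cycle (−0.11) and differentiation inhibitor (−0.08) lists lie to the left.

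OPC identity genes showed no common shift. The 18 measured markers were split 9 to 9, with a median log2 ratio of 0.00 (−0.10 to 0.15, percentile 52.9), and the read interval lay above 1 for 4 and below 1 for 6. Pdgfra, the PDGF receptor of OPCs, was at 23.2 and 24.6 TPM (read ratio 0.931, 0.867 to 0.999), and the lineage factor Olig2 at 336 and 375 TPM (0.890, 0.864 to 0.917). Cspg4, which encodes the NG2 proteoglycan, was higher with Aβ at 6.65 and 3.70 TPM (1.78, 1.54 to 2.05), as was C1ql1 (1.95, 1.32 to 2.91), while Cacng4 was at 1.43 (0.994 to 2.07). Sox10 had 22 and 33 reads (0.665, 0.369 to 1.18).

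Of 11 measured markers of committed and newly formed oligodendrocytes, 9 were lower with Aβ and 2 higher, with a median log2 ratio of −0.16 (−0.49 to 0.01) at percentile 0.38, and the read interval lay below 1 for 4 members and above 1 for 0. Mycl was at 0.679 (0.577 to 0.797), Casr at 0.816 (0.715 to 0.932), Itpr2 at 0.843 (0.795 to 0.894) and Nkx2-2 at 0.758 (0.484 to 1.18). Myelin and mature oligodendrocyte genes had a median of −0.04 (−0.30 to 0.04, percentile 14.0), with 13 of 23 lower and 9 higher. The read interval lay below 1 for 8 and above 1 for 2. Apod (0.586, 0.445 to 0.769), Evi2a (0.580, 0.388 to 0.855), Aspa (0.646, 0.436 to 0.95) and the myelin regulator Myrf (0.710, 0.573 to 0.879) were lower. Cldn11 was at 0.653 (0.422 to 1.00). For these myelin protein genes the interval included 1, with Mbp at 1.07 (0.901 to 1.27) and Mog at 0.842 (0.685 to 1.04), each under 16 TPM in both libraries.

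The list named inhibitors of oligodendrocyte differentiation had a median log2 ratio of −0.08 (−0.24 to 0.07, percentile 1.72), with 15 of 23 lower and 8 higher, and the read interval lay above 1 for 4 and below 1 for 5. As fixed, the list also held the BMP antagonists Chrd and Nog and the Wnt antagonists Wif1 and Apcdd1. Its median therefore does not describe inhibitors alone. The Notch ligand Jag1 (1.35, 1.18 to 1.55) and Id4 (1.34, 1.09 to 1.67) were higher with Aβ, and the Notch target Hes5 was lower on 4 and 15 reads (0.266, 0.0643 to 0.835). Disease-associated oligodendrocyte genes had a median of 0.02 (−0.08 to 0.20, percentile 71.2, 12 measured), and the read interval lay above 1 for 1 and below 1 for 3. In that list the complement gene C4a, on divided reads, was lower with Aβ (0.545, 0.351 to 0.836), Fxyd1 was at 1.33 (0.922 to 1.93) and Steap3 at 1.17 (0.927 to 1.47). Amyloid and Alzheimer-associated genes had a median of 0.03 (−0.05 to 0.10, percentile 78.3, 18 measured) and a read interval above 1 for 5 and below 1 for 1. App, the Aβ precursor, was at 230 and 222 TPM (1.04, 1.00 to 1.07), Ptk2b at 1.31 (1.08 to 1.60), Mapt at 1.19 (1.04 to 1.36), Psen2 at 0.837 (0.648 to 1.08) and Abca7 at 0.804 (0.585 to 1.1).

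Cell cycle genes were slightly lower with Aβ. Of 32 measured, 28 were lower and 4 higher, with a median log2 ratio of −0.11 (−0.14 to −0.05), or 0.929-fold, at percentile 0. The read interval lay below 1 for 20 and above 1 for 1. The mitotic genes Birc5 (0.789, 0.696 to 0.893), Plk1 (0.803, 0.754 to 0.856) and Cenpf (0.820, 0.783 to 0.858) stood lowest, and cyclin D2 (Ccnd2) was higher (1.17, 1.06 to 1.29). The p53 and senescence list had a median of 0.00 (−0.06 to 0.11, percentile 34.2, 22 measured), with Gdf15 at 1.91 (1.26 to 2.95) on divided reads, the cell cycle inhibitor Cdkn1a at 1.15 (1.08 to 1.22), Cdkn2a at 1.27 (0.824 to 1.97) and Igfbp5 at 0.872 (0.813 to 0.935).

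Actomyosin and contractile genes lay at equality as a group in transcript level, which does not measure contraction. Of 37 measured, 18 were higher and 19 lower, with a median log2 ratio of 0.00 (−0.07 to 0.03) at percentile 45.8. The read interval lay below 1 for 10 and above 1 for 3. The small GTPase Rhoa, which drives contraction through its kinases, was at 724 and 735 TPM (read ratio 0.95, 0.923 to 0.977), Rock1 at 0.918 (0.864 to 0.977) and Rock2 at 0.977 (0.926 to 1.03). The myosin light chain Myl9 had 42 and 50 reads (0.838, 0.542 to 1.29), Tagln 33 and 30 (1.1, 0.649 to 1.86), Cnn1 15 and 10, and smooth muscle actin Acta2 0 and 2. Vimentin (Vim) was lower, at 4236 and 5151 TPM (0.820, 0.812 to 0.828), and Cnn2 was at 0.830 (0.681 to 1.01). The non-muscle myosin gene Myh9 was listed at 0.791 (0.756 to 0.829) and Myh9l1 at 2.73 (2.44 to 3.05). Both had divided reads, and their sum of 4466 and 4587 reads, taken after these values were seen, gave 0.971 (0.932 to 1.01).

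Other cytoskeletal and adhesion lists also had medians near 0. The SRF and YAP targets had a median log2 ratio of 0.00 (−0.25 to 0.06, percentile 42.3, 14 measured), with Amotl2 (0.737, 0.642 to 0.846), Ptrf (0.805, 0.682 to 0.948) and Nuak2 (0.824, 0.695 to 0.977) lower and Thbs1 at 1.19 (0.995 to 1.43). Among these targets the read interval lay below 1 for 4 and above 1 for 0. The Arp2/3, WAVE and actin turnover list had a median of −0.02 (−0.04 to 0.01, percentile 18.6, 26 measured). Wasf1 (0.904, 0.822 to 0.993), Wasf2 (0.881, 0.812 to 0.955) and Arpc4 (0.904, 0.845 to 0.968) were lower and Cfl2 higher (1.08, 1.03 to 1.12). Integrins and focal adhesion genes had a median of 0.00 (−0.05 to 0.11, percentile 40.2, 19 measured), with Tns1 (1.53, 1.35 to 1.73) and the fibronectin receptor subunit Itga5 (1.33, 1.23 to 1.44) higher and Parva (0.893, 0.837 to 0.952) and Bcar1 (0.905, 0.837 to 0.978) lower. Matrix genes had a median of 0.03 (−0.06 to 0.12, percentile 77.9, 35 measured) and a read interval above 1 for 9 and below 1 for 6. The proteases Adamts1 (154 and 90.8 TPM, 1.68, 1.62 to 1.75) and Mmp3 (1.42, 1.13 to 1.80) were higher, and the collagen genes Col1a1 (0.425, 0.258 to 0.683) and Col1a2 (0.365, 0.257 to 0.509, with divided reads) were lower, at 3.07 TPM or less. Both collagens are also on the fibroblast and meningeal marker list, which had a median of −0.30 (−0.94 to 0.39, percentile 1.49, 6 measured) and ran from −0.60 to −0.05 over 12 settings, with Mgp at 0.687 (0.543 to 0.866) and Thy1 at 1.79 (1.11 to 2.92).

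**Figure D3:**
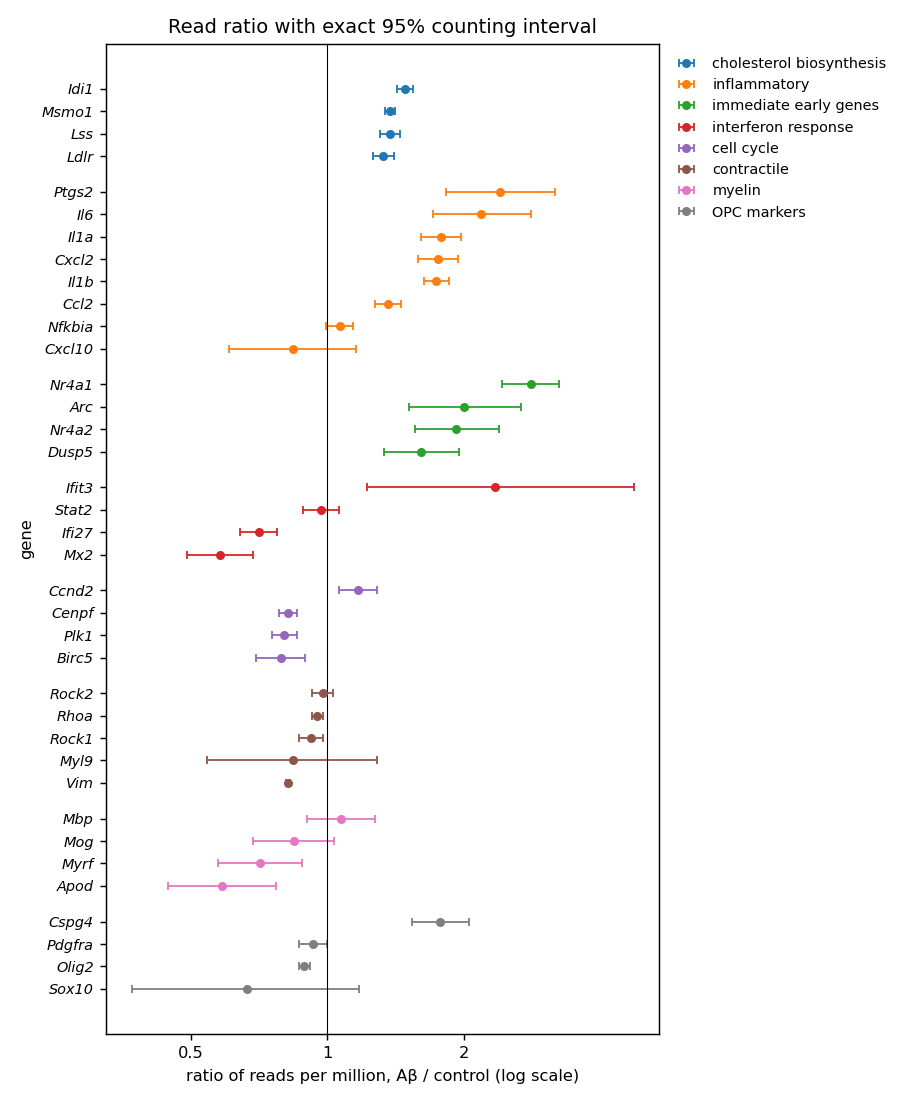
Points are the ratio of reads as a share of the library total, Aβ over control, on a log axis for selected members of 8 gene lists (colours), and bars the exact 95% counting interval; there are no replicates. The intervals of Idi1 (1.49) and Il1b (1.74) lie above 1, that of Mx2 (0.579) below 1, and those of Rock2 (0.977) and Mbp (1.07) include 1.

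Metabolic and general stress lists stayed close to equality. Glycolysis genes had a median log2 ratio of 0.04 (−0.06 to 0.13, percentile 94.4, 21 measured) and a read interval above 1 for 9 and below 1 for 5, with Eno2 at 1.79 (1.49 to 2.15) on divided reads, Hk2 at 1.20 (1.09 to 1.32), Pdk1 at 1.26 (1.03 to 1.54) and Aldoc at 1.17 (1.1 to 1.23). Oxidative phosphorylation genes had a median of 0.02 (0.00 to 0.05, percentile 89.9, 32 measured), with Ndufv2 at 1.11 (1.03 to 1.20), Ndufa2 at 1.13 (0.987 to 1.3), Ndufs3 at 1.09 (0.990 to 1.19) and Cox5b at 0.943 (0.855 to 1.04). Oxidative stress response genes had a median of 0.01 (−0.08 to 0.06, percentile 60.7, 20 measured), and the read interval lay above 1 for 6 and below 1 for 5. Thioredoxin Txn1 (1.24, 1.07 to 1.44) and glutathione reductase Gsr (1.11, 1.01 to 1.22), picked after their values were seen, were higher with Aβ. The glutathione-related genes Slc7a11 (0.857, 0.829 to 0.886) and Gclm (0.867, 0.781 to 0.962) were lower, as was Osgin1 (0.693, 0.498 to 0.959), while Mt1 was at 0.926 (0.782 to 1.1). Heat shock genes had a median of −0.01 (−0.10 to 0.03, percentile 38.9, 12 measured), with Hspe1 at 1.17 (1.08 to 1.26), Dnajb1 at 1.07 (0.981 to 1.18), Hspb1 at 0.918 (0.706 to 1.19) and Cryab at 0.844 (0.552 to 1.29). Housekeeping genes had a median of −0.01 (−0.09 to 0.05, percentile 31.8, 16 measured) and a read interval above 1 for 2 and below 1 for 3. Gapdh, with divided reads, was at 0.933 (0.918 to 0.948), Pgk1 at 0.899 (0.872 to 0.928) and Gusb at 0.904 (0.812 to 1.01).

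Markers of microglia and astrocytes went both ways. The 20 measured microglia markers were split 10 to 10 around a median log2 ratio of 0.02 (percentile 58.6), and the read interval lay below 1 for 5 and above 1 for 1. The complement gene C1qa (53.4 and 80.2 TPM, 0.672, 0.589 to 0.765), the mannose receptor Mrc1 (0.703, 0.615 to 0.802) and Aif1 (0.778, 0.635 to 0.953) were lower with Aβ, and Cx3cr1 had 15 and 27 reads (0.554, 0.274 to 1.08). Astrocyte markers had a median of −0.02 (−0.13 to 0.09, percentile 24.9, 17 measured) and a read interval above 1 for 5 and below 1 for 5. Acsbg1 (1.21, 1.14 to 1.29) was higher, the water channel Aqp4 lower (0.849, 0.804 to 0.898) and Slc7a10, on divided reads, at 1.17 (0.861 to 1.59). Pericyte and smooth muscle markers had a median of 0.10 (−0.07 to 0.70, percentile 84.5, 7 measured), and besides Cspg4 they included Anpep (1.23, 1.11 to 1.37) and Mcam (1.19, 0.953 to 1.49). Schwann cell markers had a median of −0.20 (−0.33 to 0.24, percentile 4.82, 5 measured), with Pmp22 at 1.18 (1.12 to 1.24), Pmp2 at 0.782 (0.621 to 0.983), Prx at 0.752 (0.514 to 1.09) and Drp2 at 0.793 (0.571 to 1.1). Ependymal and choroid plexus markers had a median of −0.11 (−0.96 to 0.63, percentile 23.9, 5 measured), with Foxj1 at 0.908 (0.676 to 1.22) and Dynlrb2, Mia and Ttr each at 16 or fewer reads over both libraries. Endothelial markers had a median of 0.22 (0.01 to 0.26, percentile 89.2) over the 3 measured, Flt1, Eng and Esam, none outside counting error. Of blood and T cell markers only S100a8 was measured, with 27 and 24 reads, and 0 of the 6 sex-linked transcripts were in the table.

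Sterol synthesis and the response to bacterial products headed the enrichment that accompanied the data. In the authors' deposited table, cholesterol biosynthetic process shared the lowest p-value with secondary alcohol biosynthetic process, with 17 of its 51 genes among 391 listed genes, an 11.7-fold enrichment over 13666 background genes and an adjusted p of 5.26e-11. Response to lipopolysaccharide had 30 of 296 genes, 3.54-fold and an adjusted p of 6.94e-07 in the authors' deposited table, and fever generation had 6 of 13 genes, 16.1-fold and an adjusted p of 0.000162. The 282 terms of the authors' deposited table name 246 different genes, and all 246 were higher in the Aβ library, with a median log2 TPM ratio of 0.39 (1.31-fold) and 11 at 2-fold or more. Every interval of their read ratios lay above 1, and the lowest log2 read ratio was 0.25. The enrichment is labelled as one of genes higher with Aβ, chosen on these samples, so the direction of the 246 genes was fixed in advance. Neither that direction nor the intervals above 1 are independent evidence, since the genes were chosen on the same libraries. The 246 genes included 19 of the cholesterol list, 19 of the inflammatory list and 0 of the interferon list. Genes lower with Aβ could not enter, so the 0 is not a separate result. The counts of 19 come from the same libraries and are not independent evidence either.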

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

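The settings FPKM, whole reads only, whole reads with 50 or more reads, and CPM for gene lists and named genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and no library could be left out. The counts of 65 higher and 64 lower genes became 119 and 132 with a pseudocount of 0.1, 17 and 18 with a pseudocount of 5, and 35 and 34 with a floor of 5 TPM. They were 202 and 175 at 1.5-fold, 12 and 16 at 4-fold, and 41 and 37 by CPM, the same numbers with Poisson intervals required to lie apart. Whole reads only gave 26 and 24, and whole reads with 50 or more reads and 2-fold by TPM and CPM gave 7 and 1. The stricter floors, folds and read rules keep fewer genes by construction, and the cause of the lower CPM counts was not tested.

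The cholesterol list median ranged from 0.34 to 0.37 over 12 settings, the inflammatory list from 0.25 to 0.41, immediate early genes from 0.24 to 0.35, the stress response from 0.06 to 0.12, the interferon list from −0.20 to −0.12, cell cycle from −0.12 to −0.10, committed oligodendrocytes from −0.20 to −0.10, differentiation inhibitors from −0.12 to −0.06 the lysosome list from 0.04 to 0.06 and fibroblast markers, with 6 measured, from −0.60 (5 TPM) to −0.05 (no filter). The last 4 ranges reach into the bands of the random lists (lower ends −0.11, −0.08 and −0.27, upper end 0.05 for the lysosome list), which were not recomputed per setting. Other lists of under 10 members also spread, with Schwann cell markers from −0.35 to −0.02, pericyte markers from 0.02 to 0.28, endothelial markers from 0.07 to 0.29 and ependymal markers from −0.26 to −0.07. With a pseudocount of 0.1 the endothelial median moved to 0.29 and the Schwann cell median to −0.35, and no other list median left its interval. At 5 TPM no endothelial median could be computed. The sign of the median depended on the setting for OPC, SRF and YAP, integrin, microglia, oxidative stress, p53, antigen, pattern recognition and heat shock lists, all between −0.09 and 0.09. Rescaling shifted all genes by at most 0.01 on the log2 scale. Of 1237 alternative values for 177 named genes, 15 differed from the main log2 TPM ratio by more than the log2 counting interval's radius. That radius has no upper limit for genes without reads in a library, so their values could not be among the 15. Fxyd2, counted apart from the 15, reversed from −1.35 to 0.067 by CPM, and the cause was not tested. Depth limits genes with few reads, such as Acta2, Pycard, Hes5 and Sox10.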

Other observations

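All tests of an explanation in this part, except that of few reads, and the genes of the next 3 paragraphs were chosen after the results were seen.

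Genes that neural progenitors and astrocytes also express were abundant in both cultures, and genes of the oligodendrocyte lineage ranged widely in level. Fabp7, a fatty acid binding protein of neural progenitors, was at 5661 TPM with Aβ and 6895 TPM in the control, Slc1a3, a glutamate transporter of astrocytes, at 1013 and 987 TPM, and Gfap at 328 and 368 TPM. Olig1 was at 1420 and 1557 TPM and Ptprz1 at 866 and 905 TPM. Sox10, which is on the OPC marker list, was at 0.84 and 1.22 TPM. Of the committed and newly formed oligodendrocyte markers, Gpr17 was at 0.13 TPM in both and Enpp6 at 0.22 and 0.27 TPM, while Bcas1 was at 70.7 and 81.0 TPM and Fyn at 260 and 257 TPM. The median TPM was 17.0 and 16.2 over OPC markers, 8.48 and 10.9 over committed and newly formed oligodendrocyte markers, 53.9 and 58.2 over astrocyte markers, 17.0 and 15.7 over microglia markers and 3.59 and 3.89 over myelin genes. Fabp7 (read ratio 0.849, 0.832 to 0.866), the intermediate filament gene Nes (0.859, 0.841 to 0.878) and Vim (0.820, 0.812 to 0.828) were lower with Aβ.

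Further genes outside the fixed lists, picked for their ratios, had read intervals that excluded 1. Hbegf, a ligand of the EGF receptor, had a read ratio of 1.77 (1.67 to 1.87), the matrix protein gene Spon2 of 1.64 (1.53 to 1.76), Lbh of 1.59 (1.53 to 1.66), the phosphate transporter Slc20a1 of 1.47 (1.44 to 1.51), the G protein regulator Rgs16 of 1.38 (1.34 to 1.43) and the acetyl-CoA synthetase Acss2 of 1.53 (1.45 to 1.62). Adcyap1r1, the receptor of the neuropeptide PACAP, was lower (0.694, 0.665 to 0.725), as was the ion exchanger Slc24a2 (0.427, 0.338 to 0.536). Genes expressed by myeloid cells went both ways: the surface receptors Stab1 (0.497, 0.407 to 0.605) and Cd93 (0.619, 0.550 to 0.696) were lower with C1qa and Mrc1, whereas Lyz2, at 2087 and 1661 TPM with divided reads, was higher (1.26, 1.23 to 1.29) with Cd14 and Il1b.

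TPM and reads disagreed for Lif and Fxyd2. Lif, a cytokine of the Il6 family, had a log2 TPM ratio of 0.23 but 201 and 102 reads, a read ratio of 1.97 (1.54 to 2.52). Separately, the related genes Oas1g and Oas1i were each listed at 0 in 1 library, in TPM as in reads, with 0 and 42 reads for Oas1g and 37 and 0 for Oas1i.

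Divided reads are a candidate cause for much of the 2-fold list. Genes with divided reads were 61.2% of the 2-fold genes and 13.5% of genes kept, and Tnf with LOC103694380 added to 227 and 187 reads, whole numbers in both libraries, at a ratio of 1.21. Only 5 genes of the table (0.0293%) complete Tnf to whole numbers in both, within 0.006. Of 41 further 2-fold genes with whole reads but under 50 together, 19 had a counting interval that included 1 and 22 did not. Few reads cannot be told apart from a difference for those 19. All 41 were picked as 2-fold apart in these same libraries, so an interval excluding 1 does not mark the other 22 as differences. Those 22 include Oas1g, with 0 and 42 reads, and Oas1i, with 37 and 0. The 8 genes with whole reads and 50 or more reads, such as Nr4a1 and Ptgs2, stand outside both groups by construction.

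For the higher inflammatory list, 2 technical readings were tested. A larger number of microglia would raise microglia markers as a block, but their median log2 ratio was 0.0183 with an upper bound of 0.08, under the 0.20 lower bound of the inflammatory list. Both bounds are over genes and not over cultures. Lyz2 was higher and C1qa lower, and microglia that changed in state, with or without a change in number, were not tested for. No sort is named in the labels. The length correction in TPM is argued against by the CPM median of 0.32. A difference between the 2 cultures other than Aβ cannot be told apart from Aβ, since each group has 1 library. Which cells in the cultures carried the Il1b or Il6 transcripts was not tested.

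The cholesterol list was higher in all 24 measured members. Scaling of the libraries would shift other genes of the same levels alike, but the medians of 95% of expression-matched random lists reached only 0.0482 at the upper end, under the 0.31 lower bound of the cholesterol list. That comparison restates the list's percentile of 100 and is not separate support. Other scalings shifted all genes by at most 0.01 on the log2 scale. A larger share of maturing oligodendrocytes, which make cholesterol for myelin, would raise myelin genes too, but their median was −0.0379 with an upper bound of 0.04, also under the lower bound of the cholesterol list. A culture difference such as cell density could also raise the list and cannot be told apart from Aβ here, since each group has 1 library.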
